A study of Mus musculus with 4 samples.

How the data were processed

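Transcripts of single microglia were measured in 4 libraries of male mice with a droplet assay that tags each captured molecule at its 3′ end with a unique molecular identifier (UMI). Per the labels' protocols, live CD11b+ CD45low cells were sorted by flow cytometry, 30000 from each hemibrain, and 2 hemibrains were pooled for each library. The library kit was the Chromium Single Cell 3′ kit with v2 chemistry. The labels also name an earlier time on the diet, which was not analysed here.

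The values are the deposited counts: whole numbers of UMIs per gene and cell, which the authors made with Cell Ranger 2.1.1 on mouse build mm10, per the submitters' processing notes. Per the notes with the files, the authors removed cells of low quality and then combined the 4 libraries. The deposited table holds 12800 genes and 3023 cells. Each gene has a UMI in at least 8 cells, so genes seen in fewer cells were not analysed here. The authors' file of cells gives the library and 1 of 8 clusters for each cell, and their file of genes marks 4895 genes as analysed in that clustering. The parameters of that clustering and the gene annotation behind the counts are not given in the sources used here. No further normalization was applied to the counts as deposited.

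UMIs were summed per library and divided by the library's total and multiplied by 1000000 (CPM). The sums were taken over 6 of the authors' clusters (01, 02, 04, 05, 06 and 08). Clusters 03 and 07 were left out after their leading genes had been seen. In cluster 03, which stays unnamed, those genes included Ttr, Enpp2 and 4 neutrophil markers. In cluster 07, called border-associated macrophage-like, they included MHC class II genes, 4 markers of macrophages at the brain's borders and the dendritic cell marker Cd209a. Cluster 08 stays unnamed and in the pool: 1 of its 10 leading genes, Ccl5, is a T or NK cell marker, and none is a microglia marker. The pool is therefore described by cluster number. The counts were also taken without cluster 08, a choice made after seeing the data.

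Each group holds 1 library, so no test was run between groups and no p-value or standard error is given. A ratio of 2 sums has an exact conditional binomial (Clopper-Pearson) 95% interval, a CPM an exact Poisson 95% interval and a share of cells an exact binomial 95% interval. All of these intervals cover counting error only. A gene is called at least 2-fold higher or lower by a fixed rule of size: a ratio of at least 2 or at most 0.5, an interval that excludes 1, and at least 50 UMIs over both libraries. A group at 0 UMIs is set to a floor of 3 UMIs per library. The fold is then given with that floor and is not a bound of its counting interval. The rule for named genes, written before the data were examined, takes Trem2, then the 12 higher and the 12 lower genes with at least 200 UMIs whose interval bound nearest 1 lies farthest from 1, then members of the gene lists with the most UMIs or the largest ratio. Gene models and pseudogenes were counted and not named. The comparisons, the gene lists, the cell type markers, the size rule and the alternatives were likewise fixed before the data were examined.

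Lists described homeostatic microglia, the TREM2-independent and TREM2-dependent stages of disease-associated microglia (DAM), further demyelination or disease-associated genes, cholesterol transport and LXR targets, lipid droplets and fatty acid handling, cholesterol synthesis and uptake, lysosome, phagocytosis receptors, interferon response, MHC class I, MHC class II, cytokines and chemokines, complement, TREM2 signalling partners, glycolysis, cell cycle, immediate early and dissociation response, mitochondrially encoded transcripts and cytosolic ribosomal proteins. Marker lists covered microglia and other cell types of the brain and blood. The lists come from general knowledge of the field, and some members sit in more than 1 list. The gene Clec7a of the TREM2-dependent stage was not analysed here, and of the T or NK cell markers 3 of 11 were. The list gene Lilrb4a was matched through the authors' file of genes, which pairs it with another symbol. For each list the median log2 ratio over members with at least 50 UMIs is given, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries only. A member is counted as at least 1.5-fold higher or lower where its ratio passes 1.5-fold and its counting interval excludes 1. A member whose interval holds 1 is counted as not past 1.5-fold, whatever its ratio. The interval of a median comes from 1000 Poisson redraws of the counts and covers counting error only.

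For the share of cells past a limit, each cell was thinned to 2915 UMIs, the 10th percentile of the pooled cells, and shallower cells were left out. The limit was the 95th percentile of the control-diet library, or the 5th percentile for homeostatic microglia. For clusters compared between libraries, cells were also clustered here without 398 genes: those past the size rule in any comparison and the 100 leading genes of clusters 04 and 08. That clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 0.8, with 0.4 and 1.2 as alternatives. Doublets were called per library with Scrublet in scanpy. The caller marked 7 of 571 wild-type control-diet cells, 4 of 765 wild-type cuprizone cells, 0 of 802 heterozygote cells and 1 of 885 knockout cells. Called doublets stayed in the sums, and an alternative leaves them out together with the 5% of cells with the most UMIs in each library.

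The size rule was tested on simulated counts with 50 genes changed at each fold. A 4-fold higher level was recovered for 100% of genes in each simulated comparison, and a 0.25-fold level for 86% of genes in the diet comparison, 92% in the knockout comparison and 96% in the heterozygote comparison. A true 2-fold higher level, at the edge of the rule, was recovered for 32%, 36% and 58% of genes in the same order. A 0.5-fold level was recovered for 62%, 52% and 38%. Of unchanged genes, 17 of 8594, 14 of 8985 and 12 of 9028 passed the rule. The simulated counts were Poisson draws from a common profile, with no spread between cells or animals. These rates therefore cover counting error only and are not the rule's rate of false calls in real libraries.

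Alternatives were the TMM factors of edgeR 4.0.16 and the size factors of DESeq2 1.42.0 as scalings only, other minimum counts, every deposited cell, the mean of per-cell CPM, totals without mitochondrial and ribosomal genes, and a 1.5-fold rule. Exceptions to that, chosen after seeing the data, left out cluster 08, left out the 1% of cells with the most neutrophil UMIs, kept only the genes the authors marked as analysed, used the clusters made here, or took the TREM2-dependent stage alone as a cell score. Correlations across genes and overlaps of calls were set beside 100 simulations of unchanged libraries that share the wild-type cuprizone library. The simulations for overlaps were Poisson draws from a common profile and hold counting error only. Gene positions are 1-based, from the GENCODE annotation of GRCm38, the assembly that mm10 names, matched by Ensembl identifier. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.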

Results

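Single-cell RNA-seq was carried out on microglia, the resident macrophages of the brain, from mice of 12 to 14 months that were wild type, heterozygous or homozygous for a knockout of Trem2. Trem2 encodes a receptor of microglia that binds lipids and lipoproteins and signals through the adaptor Tyrobp. The mice received a control diet or 0.2% cuprizone, a copper chelator that kills oligodendrocytes and so strips myelin, for 12 weeks. There were 4 groups with 1 library each: wild type on control diet, wild type on cuprizone, Trem2 heterozygote on cuprizone and Trem2 knockout on cuprizone. Each library pools 2 animals, so no difference below has a replicate check, and all intervals cover counting error only.

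The wild-type control library held 571 cells and 4747730 UMIs, with a median of 5220 UMIs per cell. The wild-type cuprizone library held 765 cells and 7006408 UMIs (median 6588), the heterozygote library 802 cells and 7465251 UMIs (median 6848) and the knockout library 885 cells and 7849741 UMIs (median 6488). The 6 pooled clusters kept 479, 663, 695 and 753 of these cells in the same order, with 3638474, 6175520, 6552603 and 6514310 UMIs and medians of 4717, 6588, 6849 and 6061 UMIs per cell. All 13 microglia markers had at least 50 UMIs in each of the 6 clusters.

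In the wild-type control library clusters 05, 06 and 01 held 28.8%, 28.0% and 23.2% of pooled cells. On cuprizone the largest shares of the wild-type pool were in cluster 02 (22.0%), cluster 04 (18.4%) and cluster 06 (18.4%), and those of the heterozygote pool in clusters 04 (21.6%) and 02 (20.7%). In the knockout the largest shares were in cluster 02 (28.3%) and cluster 08 (23.2%). Cluster 05 was led by Upk1b, Slc2a5 and P2ry12, cluster 06 by Upk1b, P2ry13 and Slc2a5, and cluster 04 by Spp1, Lpl and Lgals3. Cluster 08, led by Ccl5, Ifit3 and Ifit1, held 2.71%, 11.5%, 11.1% and 23.2% of the pool in the control, wild-type cuprizone, heterozygote and knockout libraries. Those leading genes had a UMI in only 28, 54 and 18 of its 341 cells, so they do not describe most of the cluster. Cluster 02 had a median of 16984.5 UMIs per cell against 3387 in cluster 01, so these 2 clusters also differ in depth. Left out of the pool were cluster 03, with 1.23%, 2.75%, 2.49% and 2.03% of each library in that order, and cluster 07, with 14.9%, 10.6%, 10.8% and 12.9%.

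Trem2 itself (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, plus strand) stood at 3132 CPM in the control library (95% Poisson interval 3074 to 3190) and 2939 CPM (2897 to 2982) in wild type on cuprizone. The heterozygote had 1763 CPM, 0.5997 times the wild-type level (0.586 to 0.614). The knockout had 520.1 CPM, 5.65-fold lower than wild type (5.45 to 5.86). The levels thus followed the genotypes in the labels. The labels do not give the allele, and a 3′ tag outside a deleted part checks nothing, so the remaining knockout UMIs do not measure functional transcript.

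**Figure D1:**
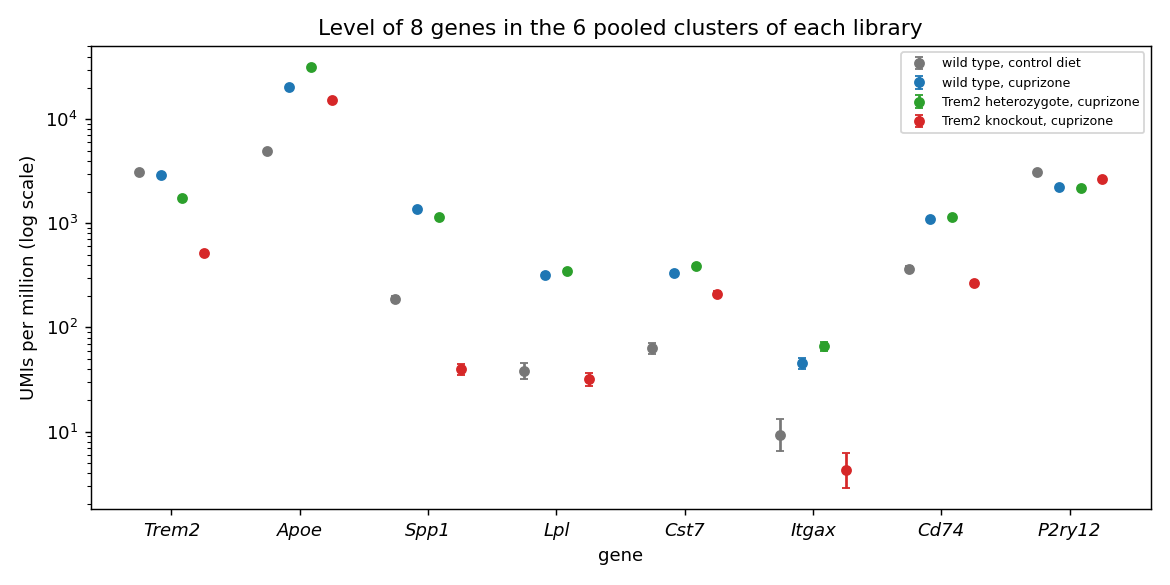
Level of 8 genes in the 6 pooled clusters of each library, in CPM on a log axis; points are the 4 libraries and bars exact 95% Poisson intervals of counting error, often smaller than the point. In the knockout, Spp1 and Lpl lay at 39.8 and 31.6 CPM, against 1369.9 and 320.1 CPM in wild type on cuprizone.

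The first comparison asked how microglia of wild-type mice differed after chronic demyelination from those on control diet. At least 1.5-fold higher on cuprizone were 3 of 7 genes of the TREM2-independent DAM stage, 7 of 10 of the TREM2-dependent stage, 13 of 14 further disease-associated genes and a few genes of lipid handling. Apoe, which encodes the main apolipoprotein of the brain, was at 20386 CPM against 4956 CPM, 4.11-fold higher (4.05 to 4.18). Lpl, a lipoprotein lipase, was 8.38-fold higher (7.05 to 10.0), Spp1, which encodes the secreted protein osteopontin, 7.29-fold (6.74 to 7.89) and the galectin gene Lgals3 9.24-fold (7.62 to 11.3). The inhibitor of lysosomal proteases Cst7 was 5.26-fold higher (4.59 to 6.06). Of 18 genes of homeostatic microglia 2 were at least 1.5-fold lower, and P2ry12, a purine receptor of resting microglia, lay nearer to 1, 1.41-fold lower (1.37 to 1.44).

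By the size rule 123 genes were higher and 52 lower of the 8819 with 50 UMIs, and 124 and 52 without cluster 08. Gene models or pseudogenes made up 4 of the higher and 17 of the lower genes. Apart from those, 44 higher and 2 lower genes had 200 UMIs and were open to naming. Besides the genes above, those named were the metalloprotease gene Mmp12 (30.8-fold, 14.8 to 77.2), the cholesterol 25-hydroxylase gene Ch25h (24.2-fold, 10.2 to 75.2), the fatty acid binding protein gene Fabp5 (7.95-fold, 5.69 to 11.4), the growth factor gene Igf1 (5.81-fold, 4.07 to 8.52), the integrin gene Itgax (4.83-fold, 3.38 to 7.12), Il4i1 (4.75-fold, 3.35 to 6.91) and the receptor tyrosine kinase gene Axl (4.604-fold, 3.67 to 5.83). A single cell held 52.5% of control Spp1 UMIs, and without the top cell of each library the ratio was 14.1; in the same way Ch25h was at 52.7. A single cell also held 35.8% of the Mmp12 UMIs on cuprizone, where the ratio without top cells was 34.6. The 2 lower genes were the transcript AY036118, 2.16-fold lower (1.99 to 2.34), and the immunoglobulin J chain gene Jchain, with 0 UMIs on cuprizone against 656. With the floor of 3 UMIs Jchain was 371-fold lower, and its counting interval began at 301-fold. A single control cell held 97.9% of those Jchain UMIs, and 14 remained without it.

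Among the lists other than cell type markers, the further disease-associated genes had the highest median log2 ratio, 2.37 (2.12 to 2.72), with 13 of 14 members at least 1.5-fold higher and a percentile of 100 among random lists. The TREM2-dependent stage followed at 1.62 (1.42 to 1.78), with 7 of 10 members higher. Its most abundant members lay nearer to 1, with Cd9 at 1.31-fold and Ctsl at 1.03-fold. In the TREM2-independent stage the median was 0.37 (0.33 to 0.40) and 3 of 7 members, Apoe, Lyz2 and Fth1, were higher. The homeostatic median was -0.34 (-0.37 to -0.31) at percentile 0, with 2 of 18 members, Klf2 and Crybb1, at least 1.5-fold lower, at 1.72-fold and 1.69-fold.

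Interferon response genes, which cells switch on against viruses and nucleic acids, were higher for 14 of 19 members, with a median of 1.103 (0.96 to 1.23). Examples were Isg15 at 3.31-fold (2.67 to 4.14) and Ifi27l2a at 2.01-fold (1.83 to 2.22). For MHC class II, which presents antigen to helper T cells, 4 of 6 members were higher and the median was 1.1995 (1.06 to 1.34), with Cd74 at 3.0004-fold (2.83 to 3.18) and H2-Aa at 2.94-fold (2.55 to 3.41). The MHC class I median was 0.18, with 0 of 10 members past 1.5-fold. Among cytokines and chemokines 7 of 15 members were higher and 1 lower (median 0.54). The neutrophil attractant Cxcl2 was 3.21-fold higher, and Ccl4 and Ccl3, which carry the most UMIs of the list, were 1.06-fold and 1.07-fold lower.

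Lipid lists showed a few members far above the rest. For cholesterol transport and LXR targets the median was 0.09 while 4 of 17 members, among them Apoe, Apoc1 (21.3-fold) and Ch25h, were higher, and the summed UMIs of the list were 3.24-fold higher. In lipid droplet and fatty acid handling 5 of 13 members were higher (median 0.33), with Fabp3 at 6.22-fold. Cholesterol synthesis had a median of 0.01 with 1 of 14 members higher, Srebf2, the transcription factor of that pathway, at 1.77-fold. Among the other lists, glycolysis had a median of 0.28, cell cycle 0.34, ribosomal proteins 0.33, mitochondrially encoded transcripts 0.21, lysosome 0.05 and immediate early genes -0.28. The last list had 2 of 15 members at least 1.5-fold lower, Klf4 and Hspa1b. Phagocytosis receptors (-0.09), complement (-0.08) and TREM2 signalling partners (-0.05) changed sign under TMM scaling, to 0.03, 0.04 and 0.06. Axl was the phagocytosis receptor with the largest ratio and C4b, at 2.104-fold, that of the complement list.

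Markers of other cell types differed as well. The 4 neutrophil markers with 50 UMIs had 0 UMIs in the control library. With the floor S100a8 was 18.5-fold higher on cuprizone, from 94 UMIs, and the list median was 3.63. Monocyte markers had a median of 1.53 (Fn1 and Ms4a4c), border-associated macrophage markers 0.26 with 4 of 10 members higher, and microglia markers -0.30. The endothelial pair went apart, with Flt1 7.27-fold higher and Pecam1 at 0.666 times the control level. Oligodendrocyte markers had a median of -0.36 and astrocyte markers -0.25. Lists with 1 measured member gave 1.53 for T or NK cells (Ccl5), -0.19 for B cells (Cd79b), -0.55 for dendritic cells (Cd209a) and 3.80 with the floor for erythrocytes (Hbb-bs). The markers of oligodendrocyte precursors, neurons, pericytes and ependymal cells had no member with 50 UMIs in this comparison.

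Under TMM scaling the median log2 ratio of all genes, -0.11 with total UMIs, became 0.01, the split went from 70.3% higher to 87.8% higher (144 higher and 20 lower), Trem2 went from -0.09 to 0.03, AY036118 from -1.11 to -0.99, and the medians to -0.22 for homeostatic genes, 0.17 for lysosome, 0.30 for MHC class I, 0.33 for mitochondrially encoded transcripts and -0.17 for immediate early genes. Over every deposited cell, which adds clusters 03 and 07, the log2 ratio was 1.23 for Apoe and 1.25 for Igf1, against 2.04 and 2.54 in the pool (Igf1 was at 3.31 without called doublets and the deepest cells and at 3.24 with the mean of per-cell CPM), and the medians were 0.18 for MHC class II, 0.73 for interferon response, 0.13 for cytokines and 1.72 for further disease-associated genes.

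**Figure D2:**
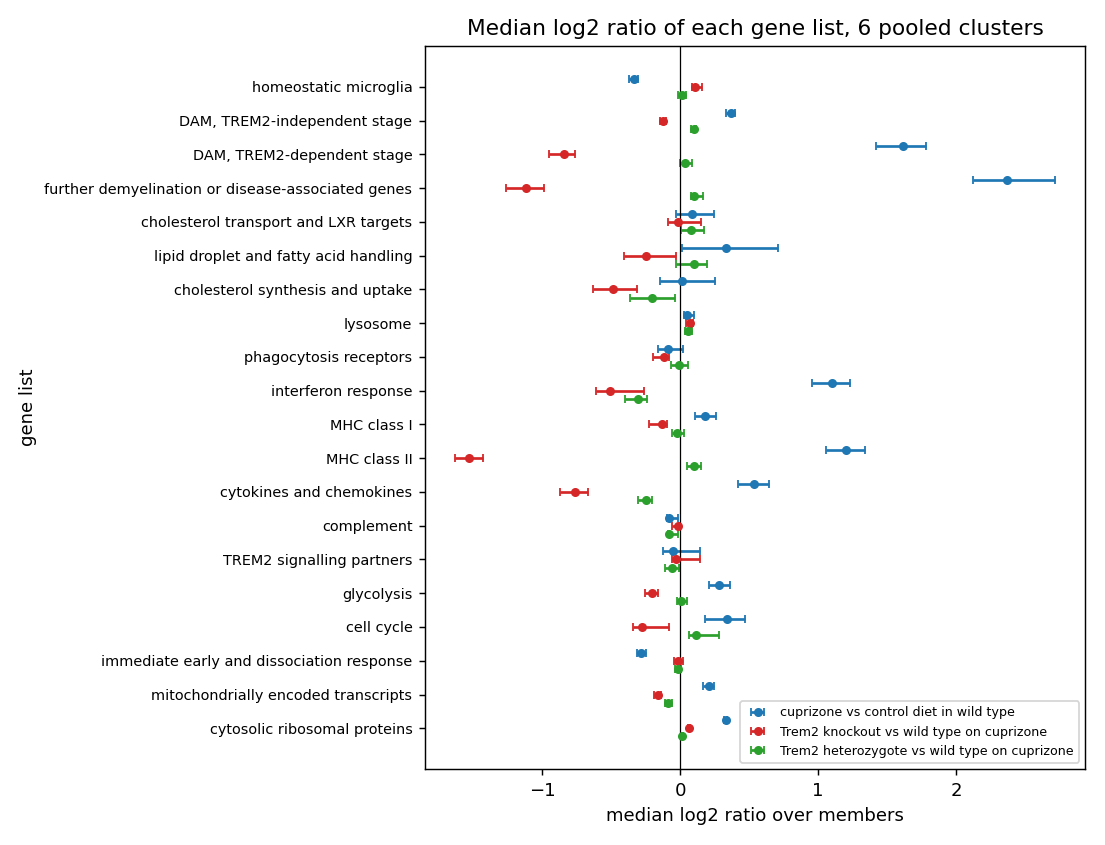
Median log2 ratio of each gene list over members with at least 50 UMIs, for the 3 comparisons in the 6 pooled clusters; bars are 95% intervals of counting error from redrawn counts. The TREM2-dependent stage lies at 1.62 for cuprizone and at -0.85 for the knockout, and MHC class II at 1.1995 and -1.53.

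The second comparison asked which genes differed between knockout and wild-type microglia on cuprizone. Many of the genes that were higher on cuprizone in wild type were lower in the knockout. Spp1 was 34.5-fold lower (30.4 to 39.1), Lpl 10.1-fold (8.77 to 11.7), Itgax 10.5-fold (7.11 to 16.1), Ch25h 13.5-fold (8.13 to 24.1) and the chemokine gene Cxcl14 12.7-fold (7.82 to 21.8). Apoe differed less, at 15283 CPM, 1.33-fold lower (1.32 to 1.35), and stayed above the control-diet level. Of 6 MHC class II genes 4 were at least 1.5-fold lower, among them Cd74 at 4.12-fold (3.91 to 4.35).

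By the size rule 36 genes were higher and 113 lower of the 9189 with 50 UMIs, and 34 and 117 without cluster 08. Gene models or pseudogenes made up 3 of the higher and 7 of the lower genes. Apart from those, 6 higher and 41 lower genes had 200 UMIs. Other lower genes named by the rule were the neutrophil attractant Cxcl2 (8.94-fold, 6.31 to 13.002), the chemokine gene Ccl7 (6.40-fold, 5.19 to 7.95), Cybb, a subunit of the phagocyte oxidase (6.31-fold, 4.74 to 8.53), Fam20c, a kinase of secreted proteins (6.003-fold, 4.31 to 8.54), Il4i1 (5.998-fold, 4.44 to 8.24) and Cd72 (5.04-fold, 3.96 to 6.49). All 6 higher genes were named. Of these, S100a8 (18.1-fold, 14.7 to 22.5), Ngp (12.4-fold, 9.31 to 16.9), S100a9 (11.1-fold, 8.78 to 14.2) and Camp (10.9-fold, 8.20 to 14.8) are neutrophil genes. A single knockout cell held 59.9% of S100a8 UMIs, and without the top cells the 4 ratios were 7.45, 6.31, 5.48 and 4.95. The other 2 were the stress-response gene Gadd45a (4.79-fold, 3.32 to 7.10) and the histone gene Hist2h2aa1 (2.502-fold, 2.09 to 3.004), whose reads can be hard to tell from those of a near-identical copy.

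The TREM2-dependent stage had a median log2 ratio of -0.85 (-0.95 to -0.77) and 7 of 10 members at least 1.5-fold lower. Beside Lpl and Itgax, Axl was 4.54-fold lower (3.81 to 5.44). The most abundant members did not share this: Cd9 was 1.03-fold and Ctsl 1.14-fold higher, and the summed UMIs of the list were at 0.949 times the wild-type level. Further disease-associated genes had a median of -1.12 (-1.27 to -0.99), with 10 of 14 members lower. In the TREM2-independent stage 0 of 7 members passed 1.5-fold and the median was -0.13 (-0.15 to -0.10). Homeostatic genes had a median of 0.11 (0.08 to 0.16), with 1 of 18 members higher, the crystallin gene Crybb1 at 1.51-fold, and Fcrls at 1.43-fold.

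MHC class II had a median of -1.53 (-1.63 to -1.43) and 4 of 6 members lower, among them H2-Eb1 at 3.51-fold (3.002 to 4.13) and H2-Aa at 3.08-fold (2.74 to 3.47). Of 10 markers of border-associated macrophages, which carry MHC class II, 5 were lower, and their median was -0.63 (-0.85 to -0.45). Interferon response genes had a median of -0.51 (-0.61 to -0.26), with 7 of 19 members lower and Isg15 at 1.88-fold. Among cytokines and chemokines 9 of 15 members were lower (median -0.77), including Cxcl16 at 2.504-fold, while Ccl4 and Ccl3 lay 1.03-fold and 1.02-fold lower. The MHC class I median was -0.14.

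For cholesterol transport and LXR targets the median was -0.02, with Abcg1, a cholesterol exporter, 1.54-fold higher (1.35 to 1.76) and Ch25h lower. Cholesterol synthesis genes had a median of -0.49 (-0.64 to -0.31) at percentile 0, with 4 of 14 members lower, among them Idi1 at 2.46-fold (1.31 to 4.85) and Srebf2 at 2.11-fold (1.46 to 3.09). In lipid droplet and fatty acid handling 3 of 13 members were lower (median -0.25), with Cd36 at 3.16-fold. Phagocytosis receptors had a median of -0.12, with 4 of 13 lower and Gas6 alone at least 1.5-fold higher. The other medians were 0.07 for lysosome, -0.02 for complement, -0.03 for TREM2 signalling partners, -0.21 for glycolysis, with Slc2a1 1.58-fold lower, -0.28 for cell cycle, -0.02 for immediate early genes, -0.16 for mitochondrially encoded transcripts and 0.06 for ribosomal proteins.

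Among other markers, the 6 neutrophil markers had a median of 3.55. Monocyte markers had a median of -0.76 over members that went both ways: Chil3 was 12.8-fold higher, with 77.8% of its knockout UMIs in a single cell, and Fn1 had 1 UMI against 53, 55.9-fold lower with an interval of 9.61 to 2249. The endothelial pair had a median of -1.54, with Flt1 10.6-fold lower (5.72 to 21.9) and Pecam1 1.26-fold higher. Medians were 0.10 for microglia markers, 0.16 for oligodendrocyte, 0.12 for astrocyte, -0.02 for T or NK cell, 0.22 for B cell, -0.14 for dendritic cell and -0.55 for erythrocyte markers.

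Over every deposited cell the medians were -0.37 for MHC class II, -0.45 for cell cycle, 0.17 for cholesterol transport and 0.06 for immediate early genes. S100a8, Ngp, S100a9 and Camp were then less than 2-fold higher, with log2 ratios of 0.52, 0.91, 0.46 and 0.34. The log2 ratios of Ccl7, Cxcl2, Cybb and Cxcl14 were -0.81, -1.24, -1.32 and -2.95, against -2.68, -3.16, -2.66 and -3.66 in the pool. Without the 1% of cells with the most neutrophil UMIs the log2 ratio was 1.15 for S100a8 and 1.28 for Ngp. S100a9 and Camp were then less than 2-fold higher, with log2 ratios of 0.89 and 0.75, and 26 genes were higher and 112 lower. Without cluster 08 the medians were 0.17 for homeostatic genes, -0.20 for the TREM2-independent stage, 0.02 for lysosome, 0.03 for ribosomal proteins and 0.05 for immediate early genes.

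**Figure D3:**
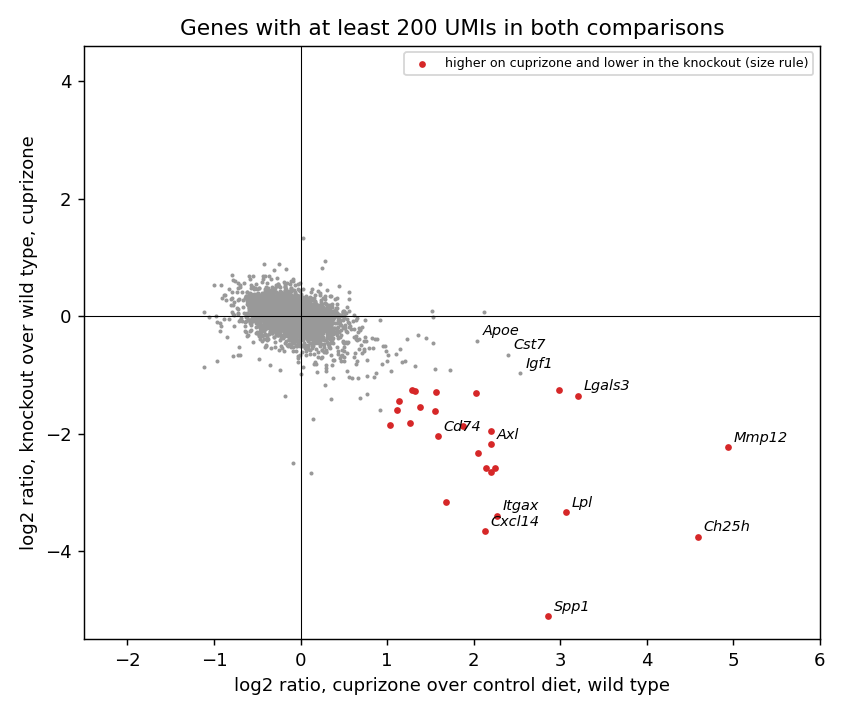
Log2 ratio of cuprizone over control diet in wild type (horizontal) against knockout over wild type on cuprizone (vertical) for 5121 genes with at least 200 UMIs in both comparisons; each point is a gene and red points are the 27 genes that were higher on cuprizone and lower in the knockout by the size rule. Spp1, Ch25h and Lpl lie at the lower right; both axes use the same wild-type cuprizone library.

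The third comparison asked how microglia heterozygous for the Trem2 knockout differed from wild type on cuprizone. Of 112 genes at least 2-fold lower in the knockout and measured in both comparisons, 9 were also at least 2-fold lower in the heterozygote. Lpl was 1.09-fold higher than in wild type (1.03 to 1.16), Cst7 1.18-fold higher (1.11 to 1.25), Itgax 1.46-fold higher (1.25 to 1.70) and Spp1 1.18-fold lower (1.15 to 1.22). Apoe was 1.55-fold higher (1.54 to 1.56), at 31627 CPM, and Apoc1, which encodes a small lipoprotein component, 1.99-fold higher (1.66 to 2.39). Of 19 interferon response genes 3 were at least 1.5-fold lower, among them Isg15 at 1.76-fold (1.53 to 2.02).

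By the size rule 42 genes were higher and 21 lower of the 9248 with 50 UMIs, and 38 and 21 without cluster 08, and 1 higher and 4 lower genes were gene models or pseudogenes. Of the 10 higher genes with 200 UMIs, 7 are neutrophil genes: S100a8 (44.4-fold, 36.2 to 55.1), Ngp (38.4-fold, 29.0 to 52.0), Camp (35.7-fold, 27.1 to 48.0), Wfdc21 (35.7-fold, 16.1 to 98.2), S100a9 (31.2-fold, 24.9 to 39.8), Lcn2 (23.7-fold, 12.2 to 52.4) and Ltf (21.6-fold, 11.9 to 43.8). The others were the heat shock genes Hspa1b (2.32-fold, 1.73 to 3.14) and Hspa1a (2.08-fold, 1.90 to 2.28), near-identical copies whose reads can be hard to tell apart, and the apolipoprotein gene Apoc4 (2.11-fold, 1.57 to 2.86). The 5 lower genes were the chemokine gene Ccl5 (2.53-fold, 2.102 to 3.05), Mmp12 (2.31-fold, 1.92 to 2.79), Pcp4 (2.09-fold, 1.69 to 2.60), the adhesion molecule gene Vcam1 (2.04-fold, 1.63 to 2.55) and the chemokine gene Ccl12 (2.03-fold, 1.91 to 2.15). The top wild-type cell of each gene held 68.4% of Ccl5 UMIs and 35.8% of Mmp12 UMIs, and without the top cells these genes were 1.73-fold and 1.72-fold lower. In the same way Vcam1 and Ccl12 fell just below 2-fold, at 1.97-fold and 1.998-fold lower, and Pcp4 was 2.21-fold lower.

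Both DAM stages lay close to wild type, with medians of 0.10 (1 of 7 members, Apoe, higher) and 0.03 (0 of 10 members past 1.5-fold). Among further disease-associated genes 3 of 14 members were higher, Apoc1, Gpnmb (1.85-fold) and Igf1 (1.53-fold), and the median was 0.10 at percentile 99.97. Homeostatic genes had a median of 0.01. The interferon median was -0.30 (-0.40 to -0.24) at percentile 0, with 3 of 19 members lower. For cytokines and chemokines it was -0.25 (-0.31 to -0.20), with 2 of 15 lower, Ccl12 and Il1rn. MHC class II had a median of 0.10, with Cd74 1.05-fold higher, and MHC class I one of -0.02.

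Cholesterol transport had a median of 0.08 with 2 of 17 members, Apoe and Apoc1, higher, and its summed UMIs were 1.499-fold higher. Cholesterol synthesis had a median of -0.21 (-0.36 to -0.04), with 1 of 15 lower, Mvd at 1.77-fold. In lipid droplet handling (median 0.10) G0s2 was 8.01-fold higher from 51 against 6 UMIs. The cell cycle median was 0.12, with 4 of 9 members higher, including Birc5 at 3.11-fold from 76 against 23 UMIs. Immediate early genes had a median of -0.02 with 2 of 15 higher, both heat shock genes, and lysosome one of 0.06, with Atp6v0d2 at 1.93-fold. The other medians were -0.01 for phagocytosis receptors, -0.08 for complement, -0.06 for TREM2 signalling partners, 0.00 for glycolysis, -0.09 for mitochondrially encoded transcripts and 0.01 for ribosomal proteins.

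Of the marker lists, neutrophil markers had a median of 5.06 and 6 of 6 members higher. Monocyte markers had a median of -0.68, with Chil3 31.1-fold higher and Fn1 1.65-fold lower. Medians were -0.03 for microglia, 0.00 for border-associated macrophages, -0.38 for oligodendrocytes, -0.33 for astrocytes, 0.11 for endothelial cells, -1.34 for T or NK cells (Ccl5), -0.24 for B cells, 0.24 for dendritic cells and -1.33 for erythrocytes (Hbb-bs).

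Without the 1% of cells with the most neutrophil UMIs, 28 genes were higher and 18 lower, and the log2 ratio of S100a8 was 2.15 against 5.47. The lists were not taken again in that setting. Whether G0s2, Birc5 and Chil3 were higher through those cells was therefore not tested. Over every deposited cell 70 genes were higher and 80 lower, and the log2 ratios were 1.62 for S100a8, -0.57 for Ccl12, -0.58 for Vcam1 and -1.54 for Pcp4. The list medians were then -0.04 for MHC class II, 0.79 for cell cycle, -0.09 for cytokines and -0.05 for glycolysis. With the mean of per-cell CPM the medians were 0.03 for cell cycle, 0.10 for the TREM2-dependent stage and 0.04 for immediate early genes.

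Cells were also scored by the share of their UMIs that a list took, after thinning to 2915 UMIs, which left 410, 604, 644 and 673 cells of the control, wild-type cuprizone, heterozygote and knockout libraries. A low homeostatic share, below the 5th percentile of control cells, was found in 33.1% of wild-type cuprizone cells (29.4 to 37.0), 35.1% of heterozygote cells (31.4 to 38.9) and 21.4% of knockout cells (18.4 to 24.7), against 5.12% of control cells. A high share of both DAM stages was found in 32.1% (28.4 to 36.0), 41.3% (37.5 to 45.2) and 30.6% (27.1 to 34.2). Apoe, Ctsd and Fth1 carry the most UMIs in this share. For cholesterol transport, which Apoe dominates, the values were 36.9%, 53.6% and 40.0%, for interferon response 14.6%, 11.6% and 11.4%, and for MHC class II 12.9% (10.3 to 15.9), 12.7% (10.3 to 15.6) and 2.53% (1.48 to 4.01). Not thinned, the shares were 34.5%, 37.6% and 21.6% for homeostatic genes, 32.0%, 40.6% and 29.6% for both DAM stages, 35.3%, 50.5% and 35.5% for cholesterol transport, 18.4%, 16.0% and 14.2% for interferon response, and 15.5%, 16.4% and 3.32% for MHC class II. Over every deposited cell the thinned shares were lower, except for MHC class II in the knockout; that list gave 6.94%, 6.75% and 3.91%. No order between wild type and knockout is read for both DAM stages or cholesterol transport: with a limit at the 90th percentile the former gave 43.7% and 45.6%, and thinned to the 25th percentile of depth the latter gave 35.7% and 34.0%.

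The TREM2-dependent stage alone was scored after the data had been seen. A high share was found in 17.2% (14.3 to 20.5) of wild-type cuprizone cells, 22.0% (18.9 to 25.5) of heterozygote cells and 22.1% (19.1 to 25.5) of knockout cells, against 4.39% of control cells. Not thinned, the shares were 21.3%, 22.3% and 24.3%. This goes against the list's median of -0.85 in the knockout. The share sums UMIs, and the abundant members Cd9, Ctsl and Timp2 were 1.03-fold, 1.14-fold and 1.37-fold higher there. Over the whole pool the list's summed UMIs were at 0.949 times the wild-type level. The median share of thinned cells was 0.515% in the knockout and 0.480% in wild type on cuprizone. The sum gives deep cells and cells far past the limit more weight, while the score counts thinned cells past it. The sum therefore cannot decide whether those members explain the difference. No order between the libraries is read from this score. All these scores are ranges of a continuous share and not cell types. Within 10% of the limit, on either side, lay 107, 99 and 117 cells of the wild-type cuprizone, heterozygote and knockout libraries for homeostatic genes, 52, 73 and 77 for both DAM stages and 71, 66 and 115 for the TREM2-dependent stage. For cholesterol transport these were 28, 24 and 47 cells, for interferon response 34, 38 and 57, and for MHC class II 7, 18 and 3.

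**Figure D4:**
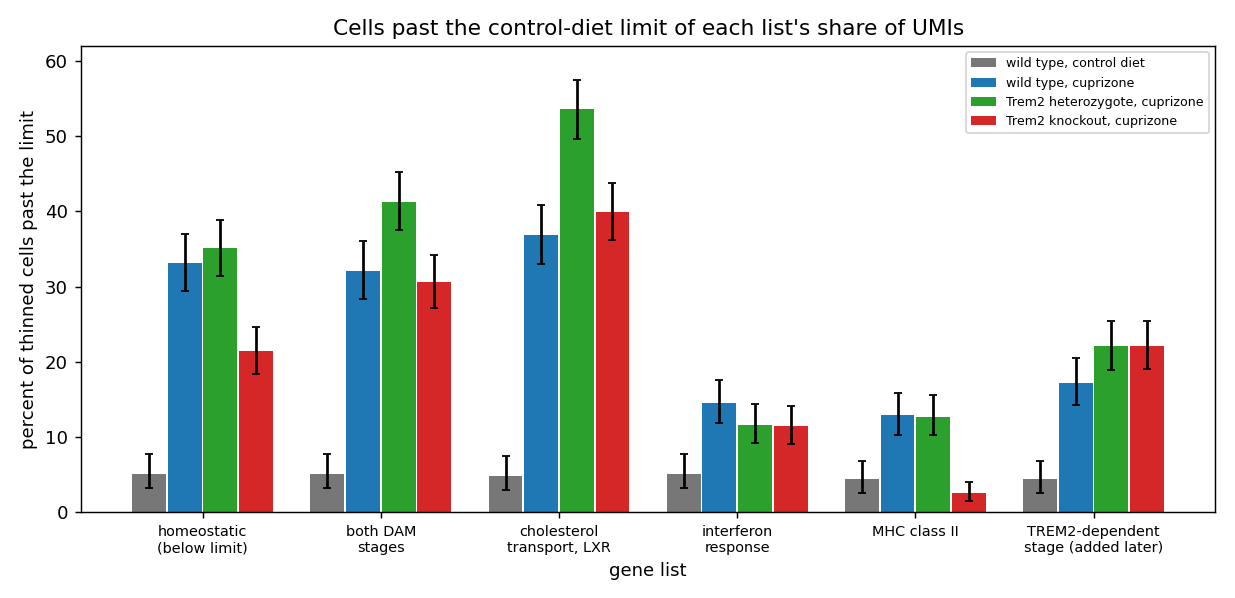
Percent of thinned cells of each library past the limit set by the control-diet library for 6 gene lists (below the 5th percentile for homeostatic genes, above the 95th for the others); bars are libraries and error bars exact 95% binomial intervals of counting error. For MHC class II the knockout lies at 2.53%, against 12.9% in wild type on cuprizone.

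Cluster 04 of the authors held 1.25%, 18.4%, 21.6% and 1.73% of the pool in the control, wild-type cuprizone, heterozygote and knockout libraries, but its leading genes are themselves among those that differ between the libraries. Clustering here without 398 such genes gave a cluster that held 59.1% of the cluster 04 cells. Cluster 04 made up 60.1% of it and cluster 08 made up 33.2%. This cluster held 2.09% of the control pool, 14.5% (11.9 to 17.4) of the wild-type cuprizone pool, 17.1% (14.4 to 20.1) of the heterozygote pool and 8.10% (6.25 to 10.3) of the knockout pool. At this resolution, 0.8, at most 30.2% of the cells of cluster 08 lay in any 1 of the clusters made here, while at 0.4 a single cluster held 58.4% of them.

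The diet and knockout comparisons share the wild-type cuprizone library, with opposite sign. Across 8803 genes, which are not independent replicates, their log2 ratios had a Pearson r of -0.469 and a Spearman rho of -0.398, where unchanged libraries that share a control gave -0.437 and -0.405. The covariance was -0.0652 against a simulated -0.0190. With the wild-type cells split at random into 2 parts, 1 for each comparison, r was -0.341 against 0.00125 simulated, and rho -0.161. Of the 123 genes higher on cuprizone, 56 were lower in the knockout, where independent lists would share 1.495 and the simulated unchanged libraries shared a mean of 0.30 and at most 3, and 4 were higher (0.182 and 0). Part of any excess over these values can come from the shared library.

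For the 46 genes that were higher on cuprizone with 200 UMIs, the median log2 level over control diet was 1.58 in wild type, 1.66 in the heterozygote and 0.31 in the knockout. In the knockout 12 of them were still at least 2-fold above control and 16 were below it, while 37 were at least 2-fold above control in the heterozygote. Choosing these genes by their wild-type cuprizone level favours higher values there than in the other libraries.

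The heterozygote was placed between wild type, set at 0, and knockout, set at 1, on the log2 scale. On that scale a gene lower in the knockout lies below 0.5 where its CPM is midway. Over the 49 genes past the size rule with 200 UMIs, gene models included, the median was 0.0474 (counting interval 0.0280 to 0.0909). The quartiles were -0.0480 and 0.295, and Trem2, itself among these genes, lay at 0.295. For the 43 of them that were lower in the knockout the median was 0.0311, with 4 genes above 0.5 and 19 below 0. For the 6 that were higher, 4 of them neutrophil genes, it was 1.37. Over the 35 members of the fixed homeostatic and DAM lists, in place of the 49 genes, it was 0.133. In the knockout 17 of 18 homeostatic members and 7 of 7 of the TREM2-independent stage did not pass 1.5-fold, while 7 of 10 of the TREM2-dependent stage did. A position divides by the knockout difference and is unstable where that is small, so 0.133 is no check of the 0.0474. The heterozygote and knockout log2 ratios had r = 0.501 and rho = 0.429 across 9105 genes, where simulated unchanged libraries gave 0.528 and 0.483, and a covariance of 0.0548 against 0.0218. With split wild-type cells r was 0.258 against 0.000105, and rho 0.105. The 2 comparisons shared 9 lower genes, against 0.258 for independent lists and a mean of 0.34 in the simulated libraries, and 19 higher genes, against 0.0860 and 0.62. Part of any excess over these values can come from the shared library. For the 19 higher genes, part can also come from a few cells with neutrophil RNA. Without the 1% of cells with the most neutrophil UMIs, 25 of the 42 higher heterozygote genes remained. Of the 36 higher knockout genes 23 remained, and the overlap was not taken again.

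Positions of 5 of the named genes, chosen after their values were seen, are as follows: Apoe (ENSMUSG00000002985) on chromosome 7 from 19696109 to 19699188 on the minus strand, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050 and Lpl (ENSMUSG00000015568) on chromosome 8 from 68880491 to 68907448, both on the plus strand. Cst7 (ENSMUSG00000068129) lies on chromosome 2 from 150570415 to 150578944 and Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812652, both on the plus strand. The annotation gives all 5 as protein-coding genes of GRCm38.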

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

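The genes in this part were chosen after their values had been seen, in clusters 03 and 07 of the authors, which the comparisons leave out. Each result given first lies above the control-diet library, no difference was tested, and intervals cover counting error only.

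In cluster 03 the neutrophil gene S100a8 stood at 24161 CPM in wild type on cuprizone (21 cells), 61651 CPM in the heterozygote (20 cells) and 47443 CPM in the knockout (18 cells). The control library had 0 of 27281 UMIs there, in 7 cells, which allows up to 135 CPM. In the 3 cuprizone libraries 5, 15 and 6 of these cells had an S100a8 UMI, in the order above, and a single cell held 36.1%, 16.5% and 28.0% of the UMIs. Ttr, a thyroid hormone carrier made by the choroid plexus, stood at 112996 CPM in wild type on cuprizone against 89330 CPM (89329.6) in the control library. It was lower than in the control library in the heterozygote, at 26770 CPM (26769.9), and in the knockout, at 42991 CPM. A single cell held 79.5%, 48.8%, 99.5% and 68.3% of the Ttr UMIs in the control, wild-type cuprizone, heterozygote and knockout libraries.

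In the border-associated macrophage-like cluster 07 Apoe stood at 42879 CPM in wild type on cuprizone, 48143 CPM in the heterozygote and 33286 CPM in the knockout, against 24333 CPM on control diet. Cd74, the invariant chain of MHC class II, stood at 11825, 10451 and 6673 CPM in the same order, against 5325 CPM. The protease inhibitor gene Cst7 stood at 97.7, 176 and 103 CPM, against 48.1 CPM. Spp1 stood at 126 CPM in wild type and 324 CPM in the heterozygote, where a single cell held 65.6% of the UMIs, against 20.3 CPM on control diet and 20.5 CPM in the knockout. Lpl stood at 71.6 CPM in the heterozygote (53.8 to 93.5) against 24.95 CPM on control diet (16.4 to 36.3), with 49.6 CPM in wild type on cuprizone (33.9 to 70.0) and a lower 12.3 CPM in the knockout (6.88 to 20.3).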

How the results depend on the processing

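Alternatives without cluster 08, without the 1% of cells with the most neutrophil UMIs, with only the genes the authors marked as analysed, with the clusters made here, with the TREM2-dependent stage as a score and, for the heterozygote and knockout correlation, with 200 UMIs were chosen after the results had been seen. No paired analysis was possible because each group holds 1 library and no test was run. Of the log2 ratios of named genes over all alternatives, 321 stayed within their counting interval and 71 moved; of the list medians 290 stayed, 69 moved and 1, outside the middle 95% of random lists, reversed. Of these 360 medians 23 lay on the other side of 0, and apart from the reversed 1 their values in the pool with total UMIs were at most 0.092 from 0. Where a cause is not given by the construction of the alternative, the cause was not tested. Depth limits what can be seen: 3 UMIs, the floor, are 0.825 CPM in the control pool and 0.486 CPM in the wild-type cuprizone pool.

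Counts of genes at least 2-fold higher and lower are given in the order cuprizone diet, knockout and heterozygote. With no minimum count they were 220 and 188, 127 and 258, and 149 and 78; with 200 UMIs they were 46 and 4, 6 and 43, and 10 and 5, since fewer genes were eligible. A 1.5-fold rule gave 228 and 392, 151 and 355, and 122 and 108. Only the genes marked by the authors gave 76 and 17, 17 and 71, and 17 and 8. Fewer genes were lower on cuprizone under TMM (20), DESeq2 size factors (21) and without mitochondrial and ribosomal genes in the total (34), and more with the mean of per-cell CPM (115), which has no counting interval. That mean also gave 60 higher genes in the knockout and 71 higher and 37 lower in the heterozygote. Every deposited cell gave 70 higher and 80 lower genes in the heterozygote. All 6 counts stayed within 1.5 times without called doublets and the deepest cells, without cluster 08 and without the cells with the most neutrophil UMIs. The genes called changed more than the counts. Of the 36 genes higher in the knockout, 21, 25 and 23 were kept in these settings, in that order, and of the 113 lower 88, 97 and 104. Of the 52 genes lower on cuprizone, 32, 42 and 48 were kept, and of the 123 higher 104, 113 and 117. Other resolutions for cell classes were not run, because the classes came from the authors' clusters.

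The lists outside the middle 95% of random lists numbered 15, 14 and 11, and all 18 alternative counts stayed within 1.5 times of these. List medians for the cuprizone diet were -0.22 for homeostatic genes under both TMM and DESeq2 factors, and 0.49 and 0.48 for the TREM2-independent stage. Over every deposited cell they were 0.30 for the TREM2-independent stage, 1.32 for the TREM2-dependent stage, 1.72 for further disease-associated genes, 0.73 for interferon response and 0.18 for MHC class II. With the mean of per-cell CPM they were 0.29 for the TREM2-independent stage and 1.34 for MHC class II. For the knockout, every deposited cell gave -0.93 for further disease-associated genes, 0.17 for cholesterol transport and -0.37 for MHC class II. The mean of per-cell CPM gave 0.072 for homeostatic genes, -0.63 for the TREM2-dependent stage, -0.84 for further disease-associated genes and -1.75 for MHC class II. Leaving out cluster 08 gave 0.17 for homeostatic genes, -0.20 and -1.06 for the TREM2-independent and TREM2-dependent stages, and -1.38 for further disease-associated genes. In the heterozygote, every deposited cell gave -0.21 for interferon response and reversed MHC class II to -0.039, and the mean of per-cell CPM gave 0.10 for the TREM2-dependent stage.

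Shares of cells past a limit are given for wild type on cuprizone, heterozygote and knockout. Over every deposited cell, where the control library's cells of clusters 03 and 07 also set the limit, they were 17.6%, 18.8% and 9.22% for homeostatic genes, 21.0%, 32.8% and 18.3% for both DAM stages, 15.3%, 27.0% and 11.2% for cholesterol transport and 9.25%, 7.69% and 5.05% for interferon response. MHC class II was then at 6.94%, 6.75% and 3.91%. With a limit at the 90th percentile, which lets more cells pass, they were 41.2%, 42.2% and 29.3% for homeostatic genes, 43.7%, 52.8% and 45.6% for both DAM stages and 17.9%, 15.5% and 15.9% for interferon response. Cholesterol transport was then at 43.0% in wild type and 48.0% in the knockout, and MHC class II at 17.5%, 18.2% and 3.86% in the 3 libraries. Thinned to the 25th percentile of depth, both DAM stages were at 39.6%, 49.7% and 36.5%, cholesterol transport at 35.7%, 54.2% and 34.0%, with the knockout below wild type as over every deposited cell, and MHC class II at 17.9% in the heterozygote. Not thinned, interferon response was at 18.4%, 16.0% and 14.2%, cholesterol transport at 35.5% in the knockout and MHC class II at 16.4% in the heterozygote. The TREM2-dependent stage alone gave 17.2%, 22.0% and 22.1%.

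The cluster made here with the most cluster 04 cells held 14.5%, 17.1% and 8.10% of the wild-type cuprizone, heterozygote and knockout pools at resolution 0.8, 12.97%, 15.5% and 8.10% at 0.4, and 13.6%, 16.7% and 7.44% at 1.2. The correlation of the diet and knockout comparisons was -0.568 with 200 UMIs and -0.341 with split wild-type cells, and that of the heterozygote and knockout comparisons 0.465 and 0.258. With 200 UMIs the simulated unchanged libraries that share wild type gave -0.435 and 0.525. With 200 UMIs and split cells the correlations were -0.407 and 0.333, against simulated values of -0.00034 and -0.0012. The heterozygote's position over the fixed lists was 0.133, outside the counting interval of the main value. Most members of those lists differed little in the knockout, which makes that position unstable and no check of the main value.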

Other observations

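The values of Trem2 and Apoe by cluster and the intervals of the S100a9 to S100a8 ratio were chosen after the results had been seen. No other test of an explanation was, but the patterns themselves and cluster averages pooled over the libraries had been seen before, so each explanation is a hypothesis on the same data.

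Trem2 was also lower by genotype in the border-associated macrophage-like cluster 07, outside the pool. It stood at 2576 CPM on control diet, 1970 CPM (1970.3) in wild type on cuprizone, 1187 CPM in the heterozygote and 387 CPM in the knockout. Apoe differed widely between the pooled clusters. In wild type on cuprizone it stood at 46630 CPM (46630.2) in cluster 04 and 18650 CPM (18649.9) in cluster 08, against 5941 CPM in cluster 05 and 4466 CPM in cluster 06. Cluster 08 had 47681 CPM in the heterozygote and 33059 CPM in the knockout.

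Neutrophil transcripts were higher in the pool of the heterozygote and the knockout, although the CD45low sort should remove neutrophils. The 1% of cells with the most UMIs of S100a8, S100a9, Camp and Ngp held 90.3% of these UMIs in the heterozygote and 86.4% in the knockout, but 8.46% of the 272 in wild type on cuprizone. That argues against free neutrophil RNA, spread over all droplets, as the whole source in the heterozygote and knockout, and is consistent with a few cells that carry a neutrophil's RNA. Outside those cells the 4 genes stood at 0, 41.3, 167 and 84.7 CPM in the control, wild-type cuprizone, heterozygote and knockout libraries, and S100a9 UMIs per S100a8 UMI there were 0.787 (0.567 to 1.09), 0.643 (0.550 to 0.751) and 0.657 (0.525 to 0.820) in the cuprizone libraries, with intervals that overlap those of cluster 03 (0.556, 0.529 to 0.584; 0.566, 0.548 to 0.585; and 0.547, 0.523 to 0.572). Free RNA therefore stays open for that remainder, and a difference between genotypes or between the pooled animals stays open and untested.

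The median log2 ratio of 6 MHC class II genes was -1.53 in the knockout. With cluster 04 left out, 79.2% of that median remained, at -1.21, which argues against fewer cluster 04 cells as the whole cause. By cluster the median was -1.17 in cluster 01, -1.37 in cluster 02, -0.24 in cluster 05, -0.74 in cluster 06 and -0.63 in cluster 08, and -0.04 in cluster 04, which held 13 knockout cells. Fewer border-associated macrophages among the pooled cells may contribute. The CD45low sort left such cells in the libraries: cluster 07 held 10.6% of the wild-type cuprizone library and 12.9% of the knockout library. In the pool the macrophage markers had a median of -0.63, between the bounds set for and against that explanation. The genotype itself stays open as well, and was not tested apart from the library.

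Apoe was 1.55-fold higher in the heterozygote than in wild type on cuprizone. With each cluster given its wild-type share of UMIs the ratio was 1.48 (1.47 to 1.49), which argues against more cluster 04 cells as the whole cause. Free Apoe RNA would add a like amount to each cluster, but the excess in cluster 04 was 5.56 times the mean excess of clusters 05 and 06. The excess ranged from 48.0 CPM in cluster 05 to 29031 CPM in cluster 08. Genotype and the particular animals pooled stay open and untested.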
